A study of Mus musculus with 30 samples.

How the data were processed

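RNA from duodenum and liver of mice on fructose, dextrose and control diets was sequenced, with 5 libraries for each of 6 groups. The deposited table holds raw read counts for 47069 Ensembl genes in each library, and the authors' FPKM for the same genes. Per the submitters' processing notes, the tools were TopHat2 2.0.12 with Bowtie2 2.2.3, HTSeq 0.6.1 and DESeq 1.18.0; the genome build and the annotation release were not given in the sources used here. Checked on the values, the deposited FPKM equal the counts divided by one length per gene and by the library's total count, within a tolerance of 0.001 for 100% of values. Of the genes, 27724 had a count in any library. Symbols came from the table for 22528 genes and from a reference annotation for 24232, and 309 had no symbol. Total counts per library ran from 14530137 to 19850935, so that counting error is small for all but the lowest genes; counting error does not include the spread between samples.

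Counts were analysed in R 4.3.3 with edgeR 4.0.16. Within each tissue the 15 libraries were fitted together with 3 diet groups after filterByExpr by group and TMM scaling. The robust quasi-likelihood F test was two-sided, with Benjamini-Hochberg adjustment over all genes tested in a comparison and a threshold of 0.05. The difference of a diet effect between tissues was the interaction contrast of a fit to all 30 libraries in 6 groups. No replicate block was used. Within a tissue, libraries of different diets were taken to come from different mice. For the tissue difference, the labels do not say that libraries sharing a number came from one mouse. In the deviations from group means, libraries of the same number matched each other best in at most 3 of 5 cases in any pair of groups, which leaves open whether the numbers pair the samples.

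The groups, the tests, 51 gene lists and most alternatives were chosen before the data were examined. The lists, 27 of them markers of cell types or signs of sample quality, were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 3 and a preset inter-gene correlation of 0.01. They were adjusted over the lists with at least 3 tested members in a comparison, and tested also with an estimated correlation and with fry. Some lists share members, so their results are not independent. With the estimated correlation 4 of 63 calls held, 3 of them in duodenum and 1 in liver, all for fructose against control. Without the libraries that stood apart these 4 had adjusted p of 0.0501 to 0.42 by that test, and 0 held. Genes named were those with the 6 largest rises and 6 largest falls past the threshold with a mean of at least 1 CPM, leaving out predicted genes and pseudogenes. The 4 members with the smallest p of each list that passed were added, as were 12 fixed genes of sugar handling and, for the tissue difference, the 4 largest in each direction. Of the genes so chosen, 2 are not reported here. A few further genes named for a list or a small count were chosen after their values were seen.

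The overlap of the effects of both sugars was compared with 40 simulations of unchanged groups on the same controls and with 20 splits of the controls. Alternatives were DESeq2 1.42.0, RLE and upper-quartile factors, no low-count filter and a stricter one, limma on log2(FPKM + 1) and log2(FPKM + 0.1), fits of only the diets compared, voom with sample quality weights, a replicate block, a minimum absolute log2 fold change of 1, and leaving out each library in turn. Leaving out the 3 duodenum libraries or both liver libraries that stood apart was added after seeing the data. Each comparison was repeated on 100 splits of its 10 libraries, or 60 for the tissue difference, the real split included. For the tissue difference each split moved the duodenum and liver libraries of the same diet and number together, 10 such pairs, although the fit does not pair them.

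The code was tested on simulated data, negative binomial counts with the spread of each tissue. At a 2-fold change edgeR recovered 59.7% of changed genes in duodenum, 58.2% in liver and 38.8% for the tissue difference, with 9 false calls among 135, 5 among 118 and 8 among 85. On the liver simulation DESeq2 made 26 false calls among 163. Any 2 libraries of a group differed by more than counting error (chi-square per degree of freedom at least 8.23), and correlations within a group ran from 0.973 to 0.998.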

Results

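Gene expression was measured by RNA sequencing in the duodenum and the liver of C57BL/6 mice given fructose, dextrose (the D form of glucose) or a control diet. Each of the 6 combinations of tissue and diet had 5 libraries, 30 in all. The total count of a duodenum library was 16519312 to 18699454 on fructose, 15473405 to 19850935 on dextrose and 15656136 to 16916063 on control. In liver it was 14530137 to 16232401 on fructose, 15579106 to 17723801 on dextrose and 16912475 to 19285480 on control. The labels do not say that the libraries came from separate mice, so the p-values measure the spread between these samples.

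Markers of the main cell type followed the tissue labels in all 30 libraries. The mean of the enterocyte list was 11.75 to 11.94 log2(CPM + 1) across the duodenum groups and 4.88 to 4.92 across the liver groups, and that of the hepatocyte list was 12.51 to 12.55 in liver and 1.62 to 2.35 in duodenum. Several libraries stood apart from their group. The pancreatic acinar list (digestive enzyme genes) had a mean of 3.00 in duodenum control 3, against 0.56 to 0.61 in the other controls, and 2.18 in duodenum fructose 3, against 0.51 to 0.6. The hepatocyte list had a mean of 4.66 in duodenum control 5, against 1.54 to 1.95. The cell cycle list had a mean of 3.95 in liver dextrose 5 and 3.9 in liver control 2, and 1.48 to 1.89 in the other libraries of those groups. Counts for each comparison are therefore also given without the 3 duodenum or both liver libraries, a choice made after seeing the data.

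**Figure D1:**
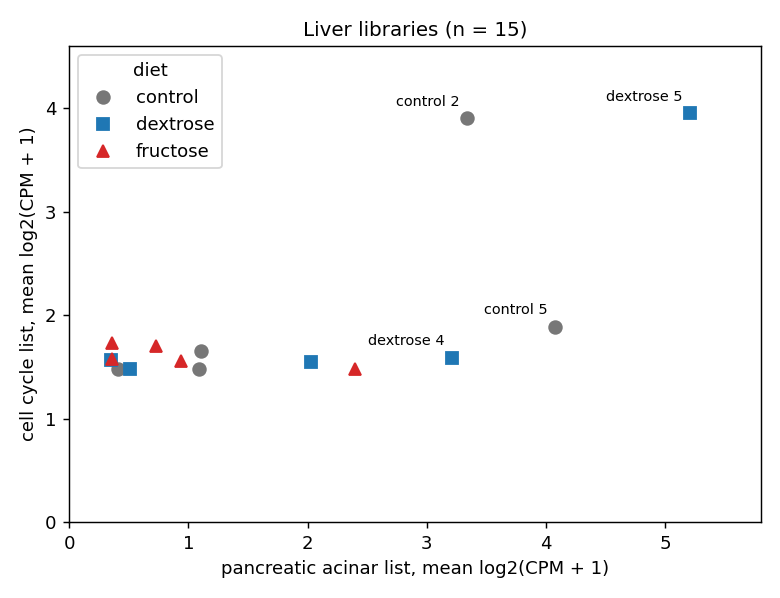
Mean of the cell cycle list (y axis) against the mean of the pancreatic acinar list (x axis), both in log2(CPM + 1), for the 15 liver libraries, each a point coloured by diet. Dextrose 5 and control 2 had cell cycle means of 3.95 and 3.9, whereas control 5, with an acinar mean of 4.08, had a cell cycle mean of 1.89.

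The first comparison asks what fructose changed in the duodenum relative to the control diet. Genes of fructose uptake and breakdown rose. Slc2a5 (ENSMUSG00000028976), the fructose transporter of the brush border, rose from a mean of 317 to 2561 TMM-scaled CPM, a log2 fold change of 3.02 ± 0.19 (SE, n = 5 per group, adjusted p = 4.39e-08). By library, with TMM factors from all genes of the tissue, all 5 fructose libraries (2250 to 2790 CPM) lay above every control library (228 to 411 CPM). Downstream of it, ketohexokinase Khk rose by 1.12 ± 0.11 and triokinase Tkfc (ENSMUSG00000034371) by 2.01 ± 0.12 on the log2 scale. Among genes of gluconeogenesis, Fbp1 (ENSMUSG00000069805), fructose-bisphosphatase, rose by 3.52 ± 0.12 (adjusted p = 6.65e-12) and G6pc, the last enzyme of glucose release, by 1.96 ± 0.35. Slc2a2, the basolateral hexose transporter, had a log2 fold change of -0.05 ± 0.18 and Slc5a1, the sodium-coupled glucose transporter, one of 0.04 ± 0.17, with adjusted p of 0.914 and 0.933. Without single libraries, or under other scalings for Slc5a1, the sign of each turned.

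Of 12 tested members of the fructose transport and fructolysis list, 8 rose and 0 fell in this comparison (8 adjusted over the list alone; camera adjusted p = 4.81e-14, and adjusted p = 0.0277 with an estimated correlation). The glycolysis list had 12 of 18 members up and 0 down (14 adjusted over the list alone; adjusted p = 1.57e-15, and adjusted p = 0.034 with an estimated correlation). Among them were Gpi1 at 1.53 ± 0.1 and Pklr, the pyruvate kinase of gut and liver, at 1.51 ± 0.10. For targets of ChREBP, a transcription factor activated by sugar, 6 of 14 rose and 0 fell (9 adjusted over the list alone; adjusted p = 1.47e-09, and adjusted p = 0.0221 with an estimated correlation). They included Gpd1 at 1.00 ± 0.11 and acetyl-CoA carboxylase Acaca at 1.60 ± 0.29. Txnip, another target in the list, was not among them, at 82 to 121 CPM on fructose and 91.5 to 166 CPM on control. These lists overlap, so their results are not separate evidence. Khk, Tkfc, G6pc and Gpd1 are in both the ChREBP and the fructolysis list, and Pklr is in both the ChREBP and the glycolysis list. Without the 3 libraries with acinar or hepatocyte transcripts these lists missed the threshold with an estimated correlation, with adjusted p of 0.0634 for fructolysis and for glycolysis and 0.0501 for ChREBP targets. Sis, the sucrase-isomaltase of the brush border, rose by 0.89 ± 0.11. Fatty acid synthase Fasn had a log2 fold change of 0.47 ± 0.47 and Scd1 one of -0.18 ± 1.45 (adjusted p of 0.64 and 0.966). Scd1 stood at 230 CPM in duodenum control 3, against 0.567 to 60.2 in the other controls.

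**Figure D2:**
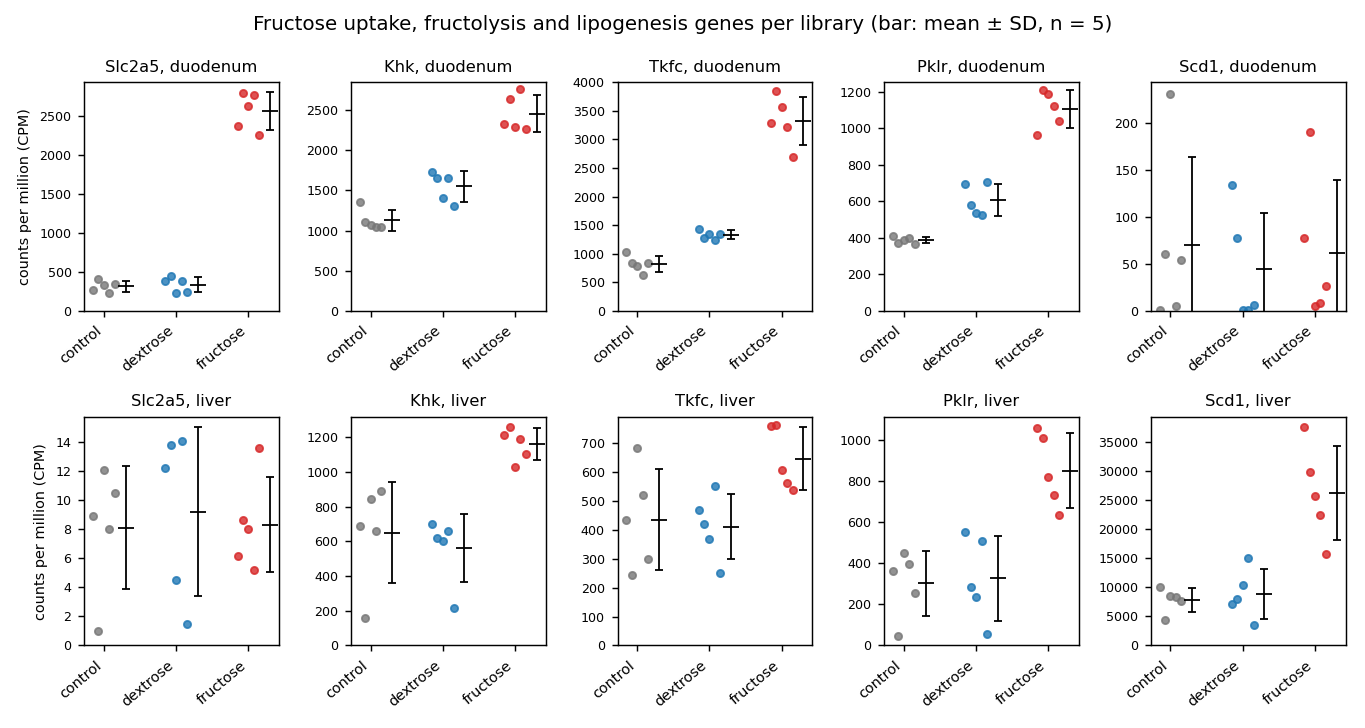
TMM-scaled CPM (y axes, linear, each starting at 0) of Slc2a5, Khk, Tkfc, Pklr and Scd1 by diet, in duodenum (top) and liver (bottom). Points are libraries, and the black bars give mean ± SD, n = 5. In duodenum, Slc2a5 lay between 2250 and 2790 CPM on fructose and between 228 and 448 CPM on the other diets; in liver, Scd1 lay between 15700 and 37500 CPM on fructose and between 4390 and 9980 CPM on the control diet.

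Interferon response genes, which limit viral replication, were also higher on fructose in the duodenum: 13 of 21 rose and 0 fell (17 adjusted over the list alone; adjusted p = 1.98e-15, and adjusted p = 0.161 with an estimated correlation). Ifi44 rose by 2.51 ± 0.30 and Ifit2 by 1.63 ± 0.27. Without the 3 libraries with acinar or hepatocyte transcripts 6 members rose, with a median log2 fold change of 0.81 over the list (adjusted p = 1.56e-13, and 0.357 with an estimated correlation). Markers of T and NK cells had a median log2 fold change of -0.65, with 0 of 10 members passing (0 adjusted over the list alone; adjusted p = 0.00723, and adjusted p = 0.893 with an estimated correlation). Without those 3 libraries they had one of -0.89 (adjusted p = 0.000143), and the Paneth cell list passed with one of -0.58 (adjusted p = 0.00742, and 0.672 with an estimated correlation).

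Peptide and amino acid transport genes fell: 7 of 13 members passed and 0 rose (8 adjusted over the list alone; adjusted p = 2.88e-06, and adjusted p = 0.466 with an estimated correlation). Slc6a19, the brush border carrier of neutral amino acids, changed by -1.33 ± 0.21, the aminopeptidase Anpep by -1.34 ± 0.24 and the peptide carrier Slc15a1 by -0.95 ± 0.17. Of these 7 members, 1 remained without the 3 libraries named above, where Anpep was at -1.162 ± 0.287 with an adjusted p of 0.0532 (over all alternatives 5.72e-07 to 0.0532) and Slc15a1 at -0.871 ± 0.216 with one of 0.0513 (1.1e-05 to 0.0513). The list as a whole had a median of -0.51 in that fit (adjusted p = 0.000129, and 0.672 with an estimated correlation).

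Several other duodenal genes fell on fructose. Slc5a12 (ENSMUSG00000041644), a monocarboxylate carrier, changed by -4.55 ± 0.70, the endocytic receptor Cubn by -3.76 ± 0.54, the lipoprotein receptor Scarb1 by -3.03 ± 0.52 and carbonyl reductase Cbr3 by -3.26 ± 0.55. In the list of lipid absorption and lipoprotein assembly 4 of 20 fell and 0 rose (6 adjusted over the list alone; adjusted p = 0.0683, and adjusted p = 0.893 with an estimated correlation). Members down were Cd36 at -1.39 ± 0.25 and the fatty acid binding protein Fabp2 at -1.08 ± 0.19. The xenobiotic metabolism list had 7 of 20 members down and 1 up (10 adjusted over the list alone; adjusted p = 0.0159, and adjusted p = 0.893 with an estimated correlation), Gstm1 among them at -2.14 ± 0.40. The steepest rise with a mean of at least 1 CPM was Slc5a8 (ENSMUSG00000020062), a sodium-coupled monocarboxylate carrier, at 5.22 ± 0.59 from 0.261 to 10.15 TMM-scaled CPM. It was followed by Adad2 at 4.12 ± 0.36 and the phosphate carrier Slc34a2 at 3.99 ± 0.73.

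Core clock genes moved in both directions on fructose in the duodenum: 4 of 16 rose and 4 fell (12 adjusted over the list alone), and the list as a whole had an adjusted p of 0.981, with a median log2 fold change of -0.53, a mean of -0.36 and a test direction of up. Without the 3 libraries with acinar or hepatocyte transcripts 2 rose and 1 fell, with a median of -0.23 (camera adjusted p = 0.809). Cry1, a repressor of the clock, rose by 1.10 ± 0.17 and Bhlhe40 by 0.98 ± 0.12, whereas Cry2 changed by -1.28 ± 0.19. The clock output gene Dbp changed by -3.84 ± 0.88 (adjusted p = 0.0166); its adjusted p was 0.0521 without duodenum fructose 4 and 0.197 without the 3 libraries named above (over all alternatives 8.72e-05 to 0.197).

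**Figure D3:**
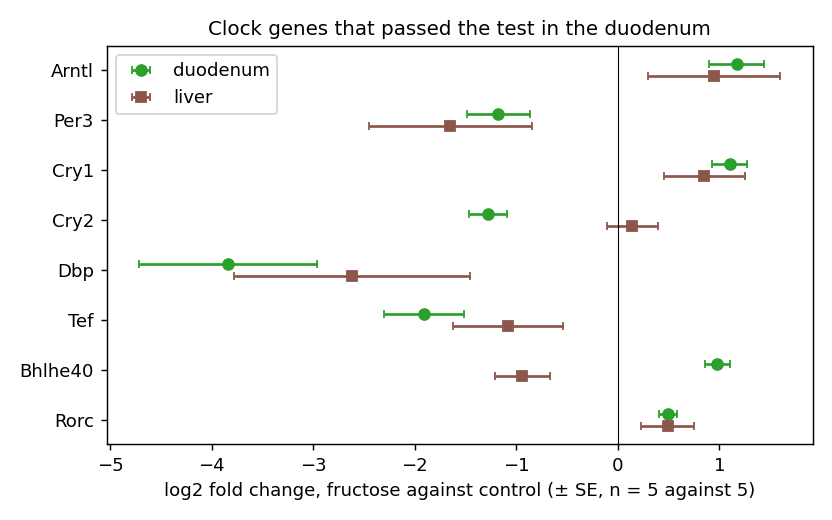
Log2 fold change of fructose against control (± SE, n = 5 per group) in duodenum and in liver for the 8 clock genes that passed in duodenum. Dbp changed by -3.84 in duodenum and had -2.62 in liver, and Bhlhe40 had 0.98 in duodenum and -0.94 in liver; 0 of the 8 passed in liver.

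By edgeR quasi-likelihood tests with Benjamini-Hochberg adjustment over 13884 genes, 932 differed between fructose and control in the duodenum, 557 of them higher and 375 lower on fructose (59.8% higher). With upper-quartile factors 480 were higher and 508 lower, and on log2(FPKM + 1) 418 and 649. Without duodenum control 3, control 5 and fructose 3, 329 genes differed, 213 higher and 116 lower, of which 325 were shared.

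The second comparison asks the same of dextrose in the duodenum. Genes of xenobiotic metabolism fell. Ugt2b5, a glucuronosyltransferase, changed by -3.13 ± 0.28 (SE, n = 5 per group, adjusted p = 4.9e-05), Gsta3, a glutathione transferase, by -4.58 ± 0.54 and the quinone reductase Nqo1 by -1.45 ± 0.17. In the xenobiotic list 10 of 20 members fell and 0 rose (12 adjusted over the list alone; adjusted p = 2.75e-22, and adjusted p = 0.059 with an estimated correlation). Por, the electron donor of cytochrome enzymes, was at -0.88 ± 0.11. Counts of the Ugt2b, Gsta, Gstm, Cyp3a and Cyp4a families are uncertain for single members, since these paralogs share sequence. The strand counted was not given in the sources used here, so values of overlapping or antisense genes are uncertain too.

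The NRF2 antioxidant list had 3 of 12 members down and 0 up on dextrose (6 adjusted over the list alone; adjusted p = 4.01e-09, and adjusted p = 0.059 with an estimated correlation), with Gclc, of glutathione synthesis, at -1.29 ± 0.15. Fatty acid oxidation and PPARA target genes fell in 5 of 22 cases and rose in 0 (13 adjusted over the list alone; adjusted p = 3.34e-15, and adjusted p = 0.169 with an estimated correlation). Examples are Cyp4a10 at -3.65 ± 0.51 and the thiolase Acaa2 at -0.83 ± 0.14. Malic enzyme Me1 changed by -3.01 ± 0.43. In lipid absorption 3 of 20 fell and 0 rose (6 adjusted over the list alone; adjusted p = 0.0399, and adjusted p = 0.913 with an estimated correlation, 0.0513 with the replicate block): Cd36 changed by -2.01 ± 0.25 and Fabp2 by -1.25 ± 0.19.

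Interferon response genes rose on dextrose too, 12 of 21 with 0 down (17 adjusted over the list alone; adjusted p = 1.78e-22, and adjusted p = 0.0669 with an estimated correlation). Ifi44 rose by 1.91 ± 0.30, Zbp1 by 1.29 ± 0.22 and Ifit1 by 1.07 ± 0.17. Without the 3 libraries, 2 of them controls, 4 members rose, with a median log2 fold change of 0.75 over the list (adjusted p = 1.92e-18, and 0.166 with an estimated correlation). In the same comparison the acinar list had a median log2 fold change of -1.14 (0 of 5 passing; 1 adjusted over the list alone; adjusted p = 0.0399, and adjusted p = 0.71 with an estimated correlation) and the hepatocyte list one of -1.47 (0 of 5 passing; 3 adjusted over the list alone; adjusted p = 0.0478, and adjusted p = 0.748 with an estimated correlation). Without the 3 libraries these lists had adjusted p of 0.424 and 0.253, and with the replicate block the hepatocyte list had one of 0.0535. The Paneth cell list had a median of -0.5 (adjusted p = 0.0399, and 0.913 with an estimated correlation), and -0.59 without the 3 libraries (adjusted p = 0.0116, and 0.89 with an estimated correlation).

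Members of the fructose transport and fructolysis list, which includes Fbp1 of gluconeogenesis, had smaller changes on dextrose. Tkfc rose by 0.69 ± 0.12, Fbp1 by 0.63 ± 0.11 and Khk by 0.46 ± 0.1, 3 of 12 members with 0 down (4 adjusted over the list alone; adjusted p = 0.000124, and adjusted p = 0.316 with an estimated correlation). Slc2a5 had a log2 fold change of 0.08 ± 0.18 (adjusted p = 0.962). The sign for Slc2a5 turned without duodenum dextrose 2 (-0.038) or control 4. Without the 3 libraries 0 of these members passed, with adjusted p of 0.0525 for Tkfc (over all alternatives 9.54e-07 to 0.0525), 0.0934 for Fbp1 (1.27e-05 to 0.0934) and 0.288 for Khk (0.00119 to 0.288). Their log2 fold changes were then 0.676 ± 0.155, 0.54 ± 0.139 and 0.396 ± 0.135, and the list had a median of 0.21 (adjusted p = 0.00219, and 0.576 with an estimated correlation). Khk also lost its call without any of 7 single libraries, at most 0.0976 without duodenum dextrose 1. The glycolysis list had 4 of 18 members up and 0 down (6 adjusted over the list alone; adjusted p = 1.61e-05, and adjusted p = 0.32 with an estimated correlation), with Pklr at 0.65 ± 0.10. Among all genes with a mean of at least 1 CPM, Cyp3a44 had the steepest rise, 2.45 ± 0.20.

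By edgeR 312 of 13884 genes differed between dextrose and control in the duodenum, 160 higher and 152 lower on dextrose. Without duodenum dextrose 1 the number was 185, and without the 3 libraries it was 163, with 59 higher and 104 lower (154 shared).

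The third comparison sets fructose directly against dextrose in the duodenum, which asks whether the sugars differ. Slc2a5 was 2.93 ± 0.19 higher on fructose on the log2 scale (SE, n = 5 per group, adjusted p = 1.62e-07), Fbp1 2.88 ± 0.12, Tkfc 1.32 ± 0.12 and Khk 0.67 ± 0.11. Fructolysis members were higher in 8 of 12 cases and lower in 0 (9 adjusted over the list alone; adjusted p = 2.5e-12, and adjusted p = 0.0533 with an estimated correlation). Glycolysis members were higher in 9 of 18 with 0 lower (9 adjusted over the list alone; adjusted p = 2.01e-11, and adjusted p = 0.0756 with an estimated correlation), and ChREBP targets were higher in 6 of 14 with 0 lower (7 adjusted over the list alone; adjusted p = 2.04e-06, and adjusted p = 0.0533 with an estimated correlation).

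Xenobiotic genes were higher on fructose than on dextrose in 7 of 20 cases and lower in 0 (14 adjusted over the list alone; adjusted p = 7.77e-10, and adjusted p = 0.151 with an estimated correlation). Ugt2b5 differed by 2.21 ± 0.28, Gstm2 by 1.65 ± 0.22 and Aldh1a1 by 1.52 ± 0.30. Epoxide hydrolase Ephx1 was 3.65 ± 0.38 higher, Me1 2.91 ± 0.43 and Slc5a8 5.88 ± 0.62. Lower on fructose were Npl, of sialic acid breakdown, at -4.07 ± 0.54 and Cubn at -3.04 ± 0.53. In amino acid transport 4 of 13 members were lower and 0 higher (7 adjusted over the list alone; adjusted p = 0.00143, and adjusted p = 0.575 with an estimated correlation), and 0 passed without the 3 libraries, where the list had a median of -0.29 (adjusted p = 0.00767, and 0.676 with an estimated correlation). Of the immediate early genes 1 of 12 was higher and 0 lower (1 adjusted over the list alone; adjusted p = 0.0028, and adjusted p = 0.4 with an estimated correlation), and of the goblet cell markers 1 of 8 was higher and 0 lower (3 adjusted over the list alone; adjusted p = 0.003, and adjusted p = 0.113 with an estimated correlation). Without the 3 libraries markers of T and NK cells (median -0.52, adjusted p = 0.0132), adipocytes (0.91, adjusted p = 0.0132) and hepatocytes (0.43, adjusted p = 0.0173) passed too, with adjusted p of at least 0.423 with an estimated correlation.

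In this comparison edgeR called 506 of 13884 genes, 301 higher and 205 lower on fructose (59.5% higher), with 282 and 329 under upper-quartile factors and 270 and 409 on log2(FPKM + 1). The number was 310 without duodenum fructose 2, 327 without duodenum dextrose 1 and 274 without the 3 libraries (270 shared).

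In the liver, fructose against control raised genes of fatty acid synthesis. The stearoyl-CoA desaturase gene Scd1 rose from a mean of 7796 to 26100 TMM-scaled CPM, a log2 fold change of 1.74 ± 0.34 (SE, n = 5 per group, adjusted p = 0.0448). ATP citrate lyase Acly rose by 2.15 ± 0.42, Acaca by 1.94 ± 0.37, Me1 by 1.82 ± 0.30 and the lipid droplet protein gene Pnpla3 by 3.83 ± 0.72. Khk had a log2 fold change of 0.83 ± 0.36, Pklr one of 1.48 ± 0.56 and Fasn one of 1.80 ± 0.53, with adjusted p of 0.388, 0.326 and 0.193. Slc2a5 had one of 0.04 ± 0.59 (adjusted p = 0.986), and its sign turned without liver control 2 or fructose 5.

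Each of these calls in liver was lost without liver fructose 2, and on leaving out 1 library at a time Scd1 and Pnpla3 lost theirs in 9 fits, Acly and Acaca in 8 and Me1 in 5. With the replicate block only 3 genes were called higher in this comparison, so some of these calls were lost there too. Without liver fructose 2 the adjusted p was 0.143 for Acly (over all alternatives 1.94e-05 to 0.143), Scd1 (3.56e-05 to 0.143), Pnpla3 (3.61e-05 to 0.17) and Acaca, the highest for Acaca in any alternative. It was then 0.09 for Me1 (9.37e-07 to 0.09). Of the 20 members of the lipogenesis list 6 rose and 0 fell (11 adjusted over the list alone; adjusted p = 2.67e-09, and adjusted p = 0.406 with an estimated correlation). The ChREBP target list had 2 of 15 up and 0 down (6 adjusted over the list alone; adjusted p = 0.000384, and adjusted p = 0.505 with an estimated correlation). It shares Acly, Acaca and Fasn with the lipogenesis list. Its member Txnip stood at 35.6 to 73.3 CPM on fructose and 41.4 to 175 CPM on control.

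Falling genes in liver on fructose were the carboxylesterase Ces1b at -1.47 ± 0.18 (adjusted p = 0.00673, over all alternatives 4.95e-10 to 0.0385), a member of a paralog family with uncertain counts, and Ildr2 at -1.33 ± 0.19 (adjusted p = 0.00896, and 0.0555 with the replicate block, over all alternatives 3.32e-08 to 0.0555). The hepcidin gene Hamp, which limits iron export, changed by -1.79 ± 0.34 (adjusted p of 0.141 without liver fructose 2 and lost without any of 9 single libraries, over all alternatives 2.65e-05 to 0.141), and the immediate early gene Egr1 by -2.03 ± 0.37 (adjusted p of 0.121 without liver fructose 3 and lost without any of 6, over all alternatives 5.85e-06 to 0.121). Immediate early genes, which also respond to handling of tissue, fell in 2 of 11 cases with 0 up (3 adjusted over the list alone; adjusted p = 7.11e-05, and adjusted p = 0.406 with an estimated correlation). Xenobiotic genes had a median log2 fold change of -0.45, with 0 of 20 passing (4 adjusted over the list alone; adjusted p = 3.04e-05, and adjusted p = 0.0301 with an estimated correlation). PPARA targets had one of -0.37, with 0 of 25 passing (3 adjusted over the list alone; adjusted p = 2.86e-07, and adjusted p = 0.406 with an estimated correlation). The acinar list had a median of -2.59 in the same comparison (0 of 16 passing; 0 adjusted over the list alone; adjusted p = 0.00139, and adjusted p = 0.809 with an estimated correlation) and the adipocyte list one of -2.31 (0 of 5 passing; 4 adjusted over the list alone; adjusted p = 0.00332, and adjusted p = 0.505 with an estimated correlation). The periportal hepatocyte list had a median of -0.23 (adjusted p = 0.0305, and 0.406 with an estimated correlation). The cell cycle list had a median of -1.47 (0 of 15 passing; 0 adjusted over the list alone; adjusted p = 0.0657). The mitochondrially encoded list had one of 0.33 (0 of 12 passing; 0 adjusted over the list alone; adjusted p = 0.0355, and adjusted p = 0.889 with an estimated correlation). Without liver dextrose 5 and control 2 it had a median of 0.22 and an adjusted p of 0.293. In that fit the cell cycle list had a median of -0.07 (adjusted p = 0.945), and the xenobiotic list had an adjusted p of 0.42 with an estimated correlation.

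In liver, fructose against control gave 34 of 13178 genes by edgeR, 25 higher and 9 lower, 232 by DESeq2 and 4 with the replicate block. The number was 6 without liver fructose 1 or 2, 8 without fructose 3, 19 without fructose 4, 17 without control 1, 7 without control 3, 62 without control 4 and 11 without control 5. It was 225 (121 higher, 104 lower, all 34 shared) without liver dextrose 5 and control 2.

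For dextrose against control in liver, which asks whether glucose alone moved the same genes, 0 of 13178 genes passed by edgeR, where 554 had an unadjusted p under 0.05 and 659 would by chance. The smallest adjusted p was 0.922, DESeq2 called 1 gene, and without liver dextrose 5 and control 2 edgeR called 0, with 1393 at an unadjusted p under 0.05. Egr1 had a log2 fold change of -1.20 ± 0.36 and Ier2 one of -0.67 ± 0.17 (SE, n = 5 per group, both with an adjusted p of 0.922). The immediate early list had a median of -0.46, with 0 of 11 passing (2 adjusted over the list alone; adjusted p = 0.000434, and adjusted p = 0.985 with an estimated correlation). The xenobiotic list had one of -0.21, with 0 of 20 passing (0 adjusted over the list alone; adjusted p = 0.00367, and adjusted p = 0.15 with an estimated correlation). On counts simulated for fructose against control with the liver spread, edgeR recovered 58.2% of genes changed 2-fold and 92.4% of those changed 4-fold. Dextrose against control was not simulated. Its groups each hold a library that stood apart, and the simulated genes, drawn independently, have no such libraries. The recovery in this comparison is therefore not known.

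Fructose against dextrose in liver asks where the sugars part. Gpi1 was 1.24 ± 0.18 higher on fructose (SE, n = 5 per group, adjusted p = 0.00973), Me1 2.03 ± 0.31 and the calcium pump gene Atp2b2 2.63 ± 0.43, and Ces1b was lower at -1.30 ± 0.18. With the replicate block 0 genes passed in this comparison, so all of these calls were lost, Ces1b with an adjusted p of 0.062 (over all alternatives 9.22e-08 to 0.062). Without liver dextrose 2 the adjusted p was 0.0508 for Gpi1 (over all alternatives 2.38e-08 to 0.0658), 0.0658 for Me1 (2.38e-08 to 0.0658) and 0.138 for Atp2b2 (3.09e-07 to 0.175). The call was lost without any of 5 single libraries for Me1 and any of 8 for Atp2b2. Scd1 had a log2 fold change of 1.58 ± 0.34 with an adjusted p of 0.107. In the lipogenesis list 1 of 20 was higher and 0 lower (10 adjusted over the list alone; adjusted p = 7.44e-08, and adjusted p = 0.441 with an estimated correlation). The MHC class II list had a median of -0.97, with 0 of 7 passing (6 adjusted over the list alone; adjusted p = 0.000219, and adjusted p = 0.484 with an estimated correlation). The acinar list had one of -3.67, with 0 of 16 passing (0 adjusted over the list alone; adjusted p = 0.000198, and adjusted p = 0.681 with an estimated correlation). Without liver dextrose 5, which had the highest acinar mean in liver (5.21), and control 2, the acinar median was -1.53 (adjusted p = 0.0535) and the MHC class II median -0.41 (adjusted p = 0.00836). With all libraries the adipocyte list (median -3.38, adjusted p = 0.000198), the periportal hepatocyte list (-0.27, adjusted p = 0.00927) and the mitochondrially encoded list (0.36, adjusted p = 0.00156) passed as well, with adjusted p of at least 0.441 with an estimated correlation. Without the pair the last 2 had an adjusted p of 0.0535.

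This comparison gave 10 of 13178 genes by edgeR, 8 higher and 2 lower on fructose, 143 by DESeq2 and 0 with the replicate block. The number was 4 without liver fructose 1, 2 or 3, 5 without fructose 4 or dextrose 1, 20 without fructose 5 and 3 without dextrose 2. It was 250 (150 higher, 100 lower, all 10 shared) without liver dextrose 5 and control 2.

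**Figure D4:**
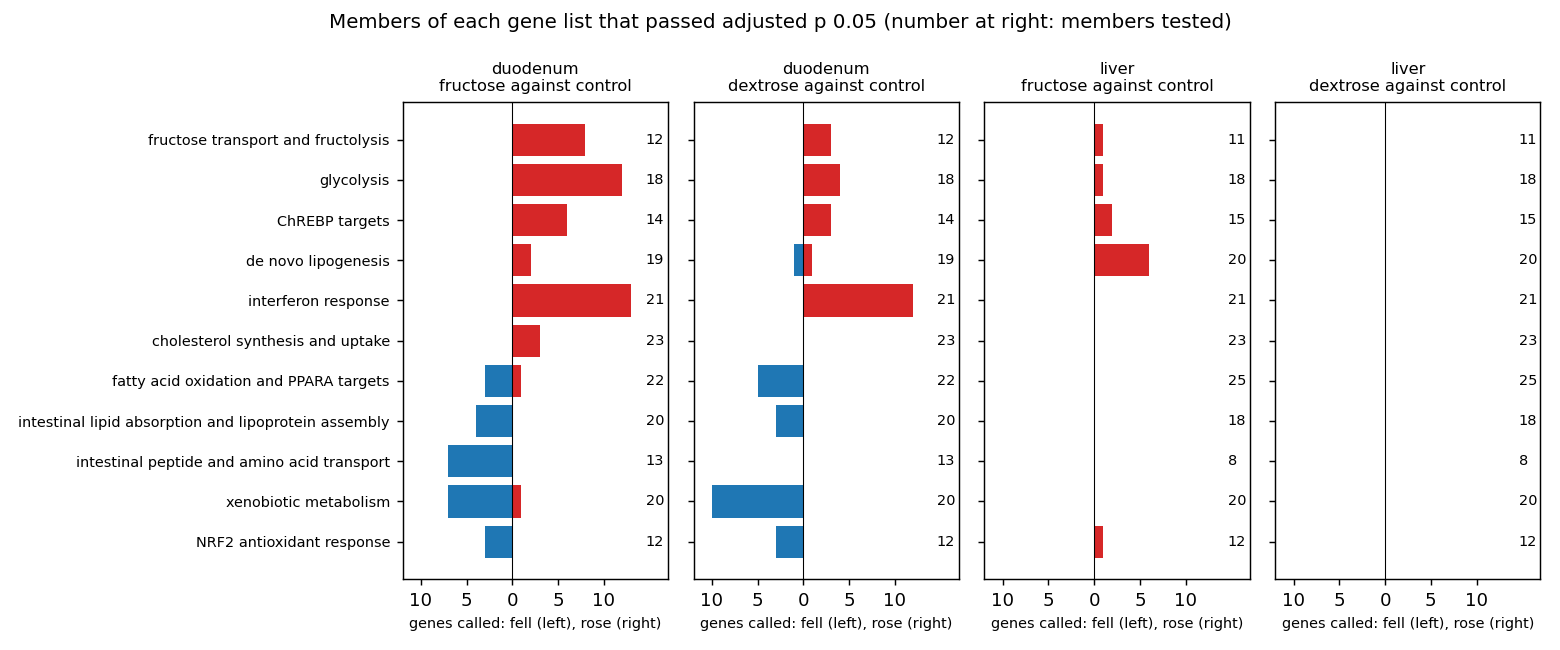
Number of members of 11 gene lists (y axis) that rose (red, right) or fell (blue, left) in fructose or dextrose against control in each tissue (4 panels, n = 5 libraries per group; the number of members tested is at the right of each panel). Fructolysis had 8 members up on fructose and 3 on dextrose in duodenum, lipogenesis had 6 up on fructose in liver, and xenobiotic metabolism had 10 down on dextrose in duodenum.

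Both sugars shared part of their effect on the duodenum. Of the genes called against control, 100 rose on both and 81 fell on both, where independent lists would share 6.4 and 4.1; 5 went opposite ways. Both comparisons use the same controls, and with the controls split between them the medians were 32.5 and 34.5, against 1.4 and 1.5 for independent lists. Over all 13884 genes the log2 fold changes had r = 0.56 across genes, which are not independent replicates, and r = 0.16 (0.04 to 0.29) with split controls. In 40 simulations of unchanged groups on shared controls r was 0.5 (highest 0.53). The simulations drew each gene independently, so their range leaves out the spread of genes that vary together. The difference between 0.56 and 0.53 therefore decides nothing. The covariance was 0.09, 0.052 above the simulated 0.039. In liver, where edgeR called 0 genes on dextrose, 0 were shared, r was 0.38 against a simulated 0.49, and the split controls gave -0.16 (-0.44 to 0.09).

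Whether a diet effect differed between the tissues was tested by its interaction, given as liver minus duodenum on the log2 scale (± SE, n = 5 per group). For fructose Scarb1 differed by 2.85 ± 0.51 (adjusted p = 0.00348), having fallen in duodenum with a log2 fold change of -0.17 in liver. Pck1, the key enzyme of gluconeogenesis, differed by 2.93 ± 0.73, an adjusted p of 0.0422 that was 0.0935 without duodenum control 2 (over all alternatives 0.0102 to 0.217, lost in 14 of 20 fits that leave out 1 library). The largest difference toward liver, Alb at 6.51 ± 1.65 (adjusted p = 0.0476), came from 2031 counts in duodenum control 5 against 1 to 9 in the other duodenum libraries, and without that library it was -0.088, with an adjusted p of 0.994 (over all alternatives 6.99e-05 to 0.994, lost in 15 of 20 fits that leave out 1 library). Clec4f, a Kupffer cell receptor, differed by 3.99 ± 0.70 but had 0 to 25 counts per library in duodenum.

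The 4 largest of 102 differences toward the duodenum on fructose, by the limits set for named genes, were Nek5 at -3.37 ± 0.62, Cyp3a44 at -4.54 ± 1.00, Mgat4c at -6.05 ± 1.46 and Sprr1a at -9.95 ± 2.11. These 4 were near the floor in liver apart from Sprr1a in liver control 2 (818 counts) and dextrose 5 (148 counts). Nek5 had 1 to 7 counts per liver library. Mgat4c had 0 in all 5 liver fructose libraries, so the liver part of its difference rests on 7 counts in liver controls and on the fit. In duodenum Mgat4c had 9 to 24 counts per control library and 60 to 129 per fructose library. Without liver control 2 Sprr1a was at -3.76 (adjusted p = 0.487, over all alternatives 0.000146 to 0.487) and Cyp3a44 at -3.49 (adjusted p = 0.228, over all alternatives 1.36e-05 to 0.228), and without liver control 3 Mgat4c had an adjusted p of 0.208 (over all alternatives 0.00201 to 0.209, lost in 16 of 20 fits that leave out 1 library).

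For dextrose the genes with the largest differences toward liver had fallen in the duodenum: Gsta3 differed by 4.29 ± 0.54 (adjusted p = 7.97e-05), Ugt2b5 by 2.92 ± 0.31 (adjusted p = 6.12e-06), Me1 by 2.78 ± 0.52 and the aldo-keto reductase Akr1b8 by 3.30 ± 0.68. Akr1b8 had an adjusted p of 0.0898 without duodenum dextrose 5 (over all alternatives 0.000338 to 0.784, lost in 12 of 20 fits that leave out 1 library). Toward duodenum were Ggh, a folate hydrolase, at -1.15 ± 0.22 and Hapln4 at -1.51 ± 0.29, which had risen there by 1.02 ± 0.14 and 1.39 ± 0.25.

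Over 15268 genes edgeR found 165 with a fructose effect that differed between tissues, 63 higher in liver and 102 higher in duodenum, and 18 for dextrose, 16 and 2. The fructose number was 106 without duodenum fructose 3, 102 without liver fructose 2 and 368 without liver dextrose 5 and control 2 (158 shared). The dextrose number was 32 without either liver dextrose 5 or liver control 2 and 35 without both (16 shared).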

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

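The tests of pancreatic, intestinal and liver RNA below, and the left-out sets of libraries, were chosen only after the result was seen. Over 27 lists, 12 genes and 4 library measures, 29 of 258 groups held a library set apart from its nearest neighbour by over 0.71 of the group's range. For normally distributed values chance gives about 5 percent, or about 1 in 20 groups. Single-gene CPM and list means near the floor need not follow that distribution, and the same library can stand apart in several groups. The comparison with 5 percent is therefore only rough.

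Liver dextrose 5 and liver control 2 stood apart, with cell cycle list means of 3.95 and 3.9 log2(CPM + 1), against 1.48 to 1.89 in the other libraries of those groups, and low pericentral hepatocyte means of 4.81 and 5.28, against 6.32 to 6.77. Pancreatic RNA may accompany this (acinar means of 5.21 and 3.34), but liver control 5, with an acinar mean of 4.08, had a cell cycle mean of only 1.89, 2.01 log2 units below the lower of the pair (-2.01), which argues against it as the source. Intestinal RNA would need shares of 87.1% and 81.1%, which imply 5730 and 5340 CPM of Sis, whereas the median excess of enterocyte transcripts was 0% of the level implied. No biological explanation was tested. Without the pair 225 genes differed between fructose and control, and leaving out 24 other pairs gave 2 to 134 (median 12.5).

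Duodenum control 5 had a hepatocyte list mean of 4.66, against 1.54 to 1.95 in the other duodenum controls. Over 85 genes found almost only in liver, its excess followed the liver level with a Spearman correlation of 0.95 across genes, and the implied share of liver RNA had a median of 0.171% (quartiles 0.153 and 0.188%). This is consistent with a small amount of liver RNA in that sample, and whether it entered at dissection or later was not tested. Leaving out this library with duodenum control 3 and fructose 3 gave 329 genes for fructose against control, and 30 other sets of 3 gave 315 to 942 (median 490), 1 of them as low.

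In liver dextrose 5 the macrophage list mean was 6.3, the Kupffer cell mean 5.27, the T and NK cell mean 1.02 and the periportal hepatocyte mean 9.37, each the highest of its group. The same library was the lowest of its group for the hepatocyte list at 11.9, the erythroid list at 3.43 and Khk at 216 CPM. The acinar list mean was 2.18 in duodenum fructose 3, 3.00 in duodenum control 3 and 2.4 in liver fructose 5. For Brunner gland markers the highest of their groups were duodenum fructose 2 at 1.3, duodenum dextrose 4 at 0.36 and liver fructose 5 at 0.5. Enteroendocrine markers stood out in liver fructose 4 at 0.2 and liver control 3 at 1.1, neutrophil markers in duodenum control 2 at 0.2 and liver fructose 5 at 0.72, and erythroid markers in duodenum fructose 2 at 1.47. Means such as 0.2, 0.36 and 0.5 lie near the floor. The other libraries of the group lay at 0.03 to 0.07 for liver fructose 4 and at 0.09 to 0.12 for duodenum control 2. Liver fructose 1 was highest for Kupffer cells at 4.75 and endothelium at 4.87, and liver control 4 for endothelium at 4.93. The immediate early list was highest in duodenum control 4 at 5.8. Khk was highest at 1350 CPM in duodenum control 1, and Scd1 at 230 CPM in duodenum control 3.

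Diet effects that differed between the tissues were found for 165 genes on fructose and 18 on dextrose. The named ones on fructose, liver minus duodenum in log2, were Alb 6.51, Clec4f 3.99, Pck1 2.93, Scarb1 2.85, Sprr1a -9.95, Mgat4c -6.05, Cyp3a44 -4.54 and Nek5 -3.37. On dextrose they were Gsta3 4.29, Akr1b8 3.30, Ugt2b5 2.92, Me1 2.78, Hapln4 -1.51 and Ggh -1.15.

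Other splits of the same libraries tested whether chance alone gives as many genes. In duodenum the real split alone (1 of 100) reached the real number for fructose against control (932, highest other 111), dextrose against control (312, highest other 10) and fructose against dextrose (506, highest other 30). In liver the same held for fructose against control (34, highest other 0) and fructose against dextrose (10, highest other 1). Chance is thus unlikely to give as many genes in these comparisons, although 1 of 100 is the smallest share that these splits can show. It is unlikely too for the tissue difference on fructose (165, highest other 2, 1 of 60 splits, which moved duodenum and liver libraries of the same number together). Every other split mixes both diets, which adds the diet difference to its spread. Nor can any split tell diet from another difference between the groups. For dextrose against control in liver the splits decide nothing, since any split reaches the real 0 (100 of 100), and the highest other gave 595. For the tissue difference on dextrose chance was not excluded, since 5 of 60 splits gave at least 18, the highest other 186. In both cases each split above the real number (10 and 4) put liver dextrose 5 and control 2 on the same side, which points to a structure of the samples.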

How the results depend on the processing

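Leaving out the 3 duodenum libraries or both liver libraries was chosen only after the result was seen; all other settings were fixed beforehand. Of 398 named gene results, 22 changed sign in some setting (43 times on leaving out 1 library and 25 times in other settings), and 1 of these, Alb, was a called value. Of calls made in the fits reported, DESeq2 kept 185 of 185, upper-quartile factors 166 of 171, log2(FPKM + 1) 158 of 168, the fits of only the diets compared 147 of 171, an absolute log2 fold change of at least 1 kept 108 of 171, voom by tissue 8 of 14, no low-count filter 157 of 185, voom with quality weights 166 of 171, the replicate block 142 of 185, and leaving out the 3 duodenum libraries 107 of 150 or both liver libraries 31 of 35. Among 63 list calls, the estimated correlation kept 4, fry 20 and the replicate block 61; without both liver libraries 21 of 30 held and without the 3 duodenum libraries 28 of 33. In duodenum, fructose against control gave 266 genes with an absolute log2 fold change of at least 1, 1466 with voom quality weights and 329 without the 3 libraries (623 to 989 on leaving out 1 library). Dextrose against control gave 113, 520 with DESeq2, 492 with voom quality weights and 163 without the 3 libraries (185 to 307), and fructose against dextrose 146, 826, 1513 and 274 (310 to 480). In liver, fructose against control gave 22 with the minimum fold change, 232 with DESeq2, 14 in the fit of these diets alone, 100 with voom quality weights, 4 with the replicate block and 225 without both libraries (6 to 62). Dextrose against control gave 1 with DESeq2 (0 to 0), and fructose against dextrose 143 with DESeq2, 16 with no filter, 18 on log2(FPKM + 1), 46 in the fit of these diets alone, 1310 with voom quality weights, 0 with the replicate block and 250 without both libraries (3 to 20). The tissue difference on fructose gave 385 with DESeq2 and 368 without both liver libraries (102 to 222), and on dextrose 90 with DESeq2, 10 with the replicate block, 10 with voom by tissue and 35 without both (13 to 32). Genes rising on both sugars in duodenum numbered 156 at a threshold of 0.1 and 32.5 with split controls, those falling 34.5, and split controls gave a correlation of 0.16 and a covariance of 0.034; in liver these were -0.16 and -0.034, the opposite sign. Shared controls and fewer samples are part of how the split is made; for all other changes the cause was not tested. List tests changed direction for the circadian clock on fructose against control in duodenum with the replicate block (adjusted p = 0.969, over the alternatives 0.809 to 0.983), and without the 3 libraries for amino acid catabolism (0.894, 0.547 to 0.965) and periportal hepatocytes (0.843, 0.8 to 0.965) in the same comparison, lipogenesis on dextrose against control (0.349, 0.349 to 0.993) and lipid absorption on fructose against dextrose (0.841, 0.841 to 0.997). Log2 fold changes that turned sign in duodenum, fructose against control, were Slc5a1 with upper-quartile factors (-0.003), on log2(FPKM + 1) and log2(FPKM + 0.1) (-0.009 in both) and with voom quality weights (-0.13), and Scd1 on log2(FPKM + 1) (0.06) and log2(FPKM + 0.1) (0.39). Scd1 (1.782), Ass1 (0.131) and Slc2a2 (0.174) turned without the 3 libraries. Leaving out 1 library gave -0.178 to 0.06 for Slc2a2, -1.249 to 1.048 for Scd1 and -0.078 to 0.15 for Slc5a1. For dextrose against control in duodenum Fasn (0.354) and Scd1 (0.988) turned without the 3 libraries, and leaving out 1 library gave -0.038 to 0.194 for Slc2a5, -0.513 to 0.205 for Fasn, -1.734 to 0.55 for Scd1 and -0.025 to 0.227 for Slc2a2. For fructose against dextrose leaving out 1 library gave -0.554 to 1.554 for Scd1. In liver, fructose against control, Slc2a5 turned with voom quality weights (-0.004) and without both libraries (-0.254), and Slc2a2 with the replicate block (0.003); leaving out 1 library gave -0.247 to 0.232 and -0.257 to 0.117. For dextrose against control Tkfc (0.028) and Slc2a2 (0.114) turned with voom quality weights, and Pklr (-0.009) with the replicate block. Leaving out 1 library gave -0.173 to 0.378 for Pklr, -0.105 to 0.467 for Slc2a5, -0.214 to 0.195 for Slc2a2, -0.113 to 0.369 for Scd1, -0.239 to 0.129 for Tkfc and -0.41 to 0.122 for Txnip. For fructose against dextrose Slc2a5 turned on log2(FPKM + 1) (0.04) and log2(FPKM + 0.1) (0.106), Slc2a2 on both (0.042 and 0.044) and with the replicate block (0.035), Slc5a1 with voom quality weights (0.131) and without both libraries (0.128), and Nqo1 without both (0.086). Leaving out 1 library gave -0.162 to 0.118 for Slc5a1, -0.267 to 0.14 for Slc2a2, -0.422 to 0.064 for Slc2a5 and -0.827 to 0.076 for Nqo1, and for the tissue difference of Alb -0.088 to 6.834. At this depth and spread, edgeR recovered 38.8% of 1.5-fold changes in duodenum, 19.4% in liver and 11.9% of those that differ between tissues.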

Other observations

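The counts without liver dextrose 5 and control 2 and the genes that moved in opposite directions were chosen only after the result was seen. Without this pair 225 liver genes differed between fructose and control and 250 between fructose and dextrose. With all libraries the replicate block gave 4 and 0, and which of these counts is nearer the truth was not tested. Against control, Atp2b2 rose by 3.05 ± 0.26 on the log2 scale (SE, adjusted p = 2.89e-05), the lipid droplet genes Pnpla3 and Pnpla5 by 3.56 ± 0.59 and 3.51 ± 0.62, and Aldh18a1, of proline synthesis, by 2.03 ± 0.36. Scd1 rose by 1.59 ± 0.25, Elovl6 by 1.6 ± 0.32, Pklr by 1.2 ± 0.25 and Khk by 0.58 ± 0.12. Ces4a changed by -1.91 ± 0.34, Egr1 by -1.64 ± 0.31 and Hamp by -1.68 ± 0.37. Fructose against dextrose gave rises of Npas2, a clock activator, by 3.46 ± 0.63 and of the cell cycle inhibitor Cdkn1a by 2.58 ± 0.48, and a change in the clock repressor Bhlhe41 of -2.88 ± 0.52. In these fits 7 lipogenesis genes rose against control and 0 fell, and 5 were higher and 1 lower against dextrose, but with an estimated correlation the list had adjusted p of 0.423 and 0.458. Lists of cell markers passed in the same fits, with adjusted p of at least 0.423 with an estimated correlation. Against control the adipocyte list had a median of -2.44 (adjusted p = 0.02), the acinar list one of -2.22 (adjusted p = 0.0317) and the periportal hepatocyte list one of -0.27 (adjusted p = 0.02). Against dextrose the adipocyte list had one of -3.57 (adjusted p = 0.00185), the pericentral hepatocyte list one of -0.23, with 2 members lower (adjusted p = 0.00808), the hepatocyte list one of -0.22 (adjusted p = 0.0462) and the cholangiocyte list one of 0.64 (adjusted p = 0.0357).

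In the duodenum 5 genes passed on both sugars in opposite directions. Ephx1 rose by 1.89 ± 0.35 on fructose and changed by -1.76 ± 0.36 on dextrose, Pmm1 by 0.9 and -0.92, Upb1 by 0.64 and -0.48 and Maff by 0.76 and -0.56. Npl changed by -2.13 ± 0.54 on fructose and rose by 1.94 ± 0.48 on dextrose.

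In the duodenum 8 clock genes passed on fructose, 4 up and 4 down, with a median size of 1.17 on the log2 scale. Without the 3 libraries with acinar or hepatocyte transcripts only 2 clock genes rose and 1 fell, so most of these calls were lost. That fit also holds fewer libraries. Leaving out 30 other sets of 3 lowered the number of all genes called from 932 to a median of 490. Whether the clock calls were lost through these libraries or through the smaller groups was not tested. For scaling as the source, 8 of 8 kept call and direction with upper-quartile and RLE factors. Those factors moved the median log2 fold change of all genes only from -0.022 to -0.056 and -0.021. Shifts so small could hardly undo changes of this size in both directions, so this test had little chance of another outcome. Another hour of collection for the fructose group may account for the clock changes, but the test is weak. In liver the same genes had a median of 0.9 ± 0.48 (SE) in the direction of the duodenum, with 6 of 8 in the same direction. This SE is the spread over the 8 genes, which are not independent samples. The median lay above the bound of 0.59 set beforehand by less than that SE. Of the 8 genes 0 passed in liver with all libraries, and Bhlhe40 (-0.94) and Cry2 (0.14) had the opposite sign there. Without both liver libraries that stood apart, 0 clock genes rose and 1 fell on fructose against control. Against dextrose 1 was then higher and 2 lower. Dbp was at -2.92 ± 1.01 against control and -3.34 ± 1.02 against dextrose in that fit, with edgeR adjusted p of 0.176 and 0.15. In duodenum the clock list had a mean of 4.1 log2(CPM + 1) on fructose, 4.13 on dextrose and 4.38 on control. On fructose its genes moved both ways, so these means decide nothing. The collection hour was not given in the sources used here, and a direct effect of fructose on the clock or on feeding time stays open, untested.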
